A study of Mus musculus with 21 samples.

How the data were processed

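Poly(A) RNA was measured by sequencing in 21 libraries of mouse bone marrow-derived macrophages, with 4 WT and 3 labelled Nur77-KO libraries at each of 0, 4 and 18 h of LPS. Per the labels' protocols, RNA was extracted with RNeasy kits and libraries were made with the KAPA mRNA HyperPrep kit. Per the submitters' processing notes, CASAVA 1.8.2 and HISAT2 2.1.0 were used with the mm10 build. The counting tool, its treatment of strand and its treatment of reads shared between genes are not given in the sources used here, so genes with near-identical copies or overlapping neighbours are uncertain. Gapdh, which has many processed copies, held only 10 to 573 counts per library. The deposited values were estimated counts per RefSeq transcript, in steps of 0.5 and not scaled to depth. The design had assumed whole-number counts, and the values were rounded to whole numbers (a value ending in 0.5 upward) before the planned count test.

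The table held 42361 transcript IDs, of which 42203 matched a RefSeq table of the mm10 assembly and 65 a GENCODE annotation. The remaining 93 had no gene name, took 0.232 to 2.229% of the counts per library and were left out of library sizes and tests. Transcripts of a gene carried nearly the same reads (8193 genes had several, with a median ratio of the second to the first of 0.9914), so the transcript with the highest mean over all libraries stood for each of 25067 genes. Deposited columns totalled 23478281.5 to 55852932 per library and the genes kept 12301504 to 29650081. Groups came from sample titles. The genotype tag of the labelled-KO libraries reads cre, and whether the knockout is germline or conditional is not given in the sources used here. No pair of libraries of a group differed by less than the sampling noise.

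The test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3 on all 21 libraries with 6 group means, trimmed mean of M-values (TMM) factors and edgeR's default expression filter, which kept 12529 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 in each comparison. Standard errors were taken as the log2 fold change divided by the square root of the F statistic, so none are given near 0. CPM values use TMM library sizes. Fixed gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with the correlation estimated. Of 42 lists, 38 had at least 5 tested genes. The called lists that held with an estimated correlation were the cell cycle and neutrophil lists at 0 h, NF-kB genes in all 4 LPS comparisons, and NF-kB and immediate early genes in the interaction at 18 h. Intervals of ratios are 95% counting intervals, and a group with no counts was set to a floor of 3 counts over the group. Both cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

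The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Nr4a1, a set of fixed genes of inflammation, matrix and cytoskeleton, up to 10 rises and 10 falls of each main comparison (adjusted p under 0.05, a mean of at least 5 CPM, groups not overlapping), up to 6 of each sign in the interactions, and up to 2 members of each sign per list. Named genes left out clone-named genes and pseudogenes. The alternatives were DESeq2 1.42.0, limma-voom with and without a correlation of same-numbered libraries, median-of-ratios factors, other filters, fits on the compared groups alone, the replicate number as a block, and leaving out each library. Added after seeing the data were upper-quartile factors, summed transcripts, the mean of the stromal list as a covariate, and fits without labelled-KO number 4 or without the library of highest stromal mean in each group.

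Whether replicate numbers pair libraries was checked by the correlation of deviations from group means. WT libraries of the same number at 0 h and 4 h correlated at 0.23, 0.32, 0.24 and 0.24 (-0.23 to 0.09 for differing numbers). Labelled-KO libraries of the same number at 4 h and 18 h correlated at 0.4, 0.1 and 0.5 (-0.48 to 0.11 for differing numbers). No other set of same-numbered pairs was at 0.1 or above throughout. The labels do not say what a number marks. In comparisons between genotypes the block joined WT and labelled-KO libraries of the same number. Those pairs correlated at -0.34 to 0.16 at the same time, which gives no ground for joining them. At 18 h WT number 3 correlated at 0.34 with WT number 2 at 0 h and at -0.12 with its own number, while WT number 2 correlated at -0.09 with its own number and at -0.1 with WT number 3 at 0 h. Whether WT numbers 2 and 3 are crossed at 18 h was not settled, and this bears on the block and on splits across times but not on comparisons of groups. Tests were run on simulated counts for the 12529 genes. Few genes were changed (67 by 1.5-fold and 67 by 2-fold), all of them well counted and as many up as down. Each gene was drawn on its own. The rates below thus do not carry over to poorly counted genes or to shifts that many genes share. With edgeR at 0 h, 68.7% of genes changed 1.5-fold and 85.1% of those changed 2-fold were recovered, with 4.21% false calls. At 4 h these were 61.2%, 89.6% and 3.63%, and at 18 h 61.2%, 89.6% and 5.98%.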

Results

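RNA was sequenced from bone marrow-derived macrophages of male mice, cells grown from marrow for 7 days in medium conditioned by L929 fibroblasts. The cells carried either wild-type (WT) Nr4a1 or a label of Nur77 knockout; Nur77 is the nuclear receptor encoded by Nr4a1. They received lipopolysaccharide (LPS), a bacterial cell wall component sensed by Toll-like receptor 4, at 100 ng/ml for 0, 4 or 18 h. There were 4 WT and 3 labelled-KO libraries at each time, 21 in all, and their counts assigned to genes totalled 12301504 to 29650081 per library. The first principal component of log2 CPM (counts scaled to the library total) held 58.8% of the variance and separated the times. The second held 26.1%. The labels give numbers to the libraries but do not state that each number is a separate mouse, so p-values measure the spread between these libraries.

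**Figure D1:**
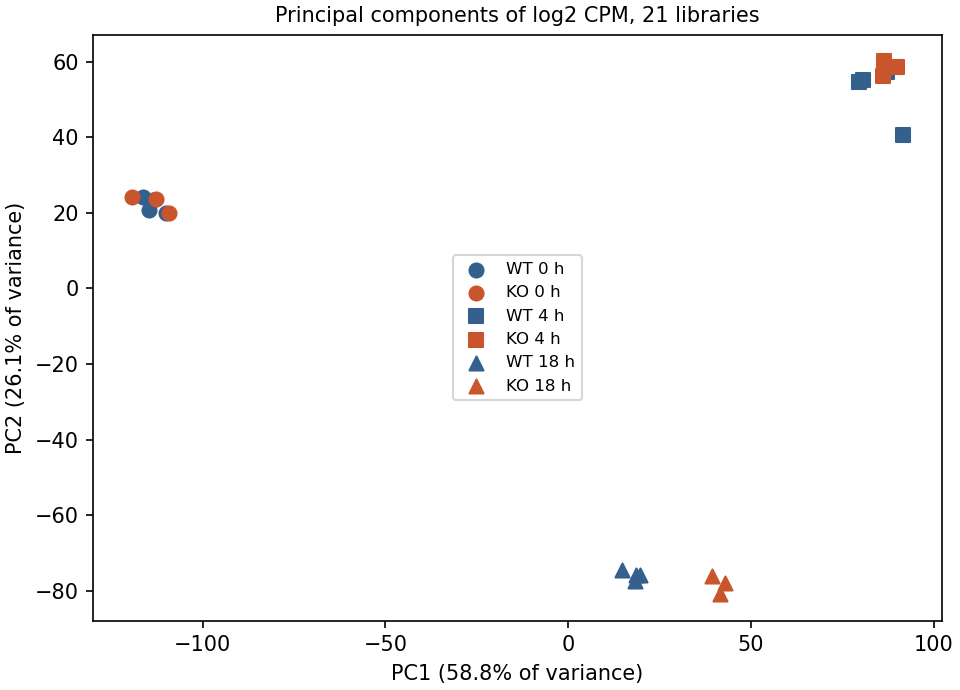
Each point is a library placed by its first 2 principal components of log2 CPM (axes, with percent of variance), with colour for labelled genotype and shape for hours of LPS. The 3 times lie apart, and at 18 h the labelled-KO libraries lie between 39.3 and 42.8 on the first component against 14.6 to 19.5 in WT.

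The targeted gene came first, since it can check the labels. Nr4a1 (NM_010444, chromosome 15, 101253902 to 101274795 on mm10) stood at 14.7 ± 1.27 CPM (SD, n = 4) in WT and 12.3 ± 0.114 CPM (SD, n = 3) in labelled KO at 0 h. That difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 fold change -0.25, adjusted p = 0.75). At 4 h Nr4a1 was 3.11 ± 2.78 CPM in WT and 0.871 ± 0.34 in labelled KO, lower by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (-1.77, adjusted p = 0.04). WT number 1 held 7.25 CPM there, against 1.3 to 2.16 in the other WT libraries, and without it the log2 fold change was -0.85 and did not pass. The call also ended without any of the 3 labelled-KO libraries at 4 h (-2.17 to -1.55). It ended with limma-voom (-1.41), with the replicate number as a block (-1.47) and with only the 4 h libraries fitted (-1.78). At 18 h Nr4a1 was higher in labelled KO, 2.85 ± 0.698 against 1.1 ± 0.159 CPM (log2 fold change 1.35, adjusted p = 0.023 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That call ended without WT number 1 (1.31) or labelled-KO number 2 (1.33) or 4 (1.16) and with the stromal covariate (0.99), the mean of a stromal marker list added after seeing the data. Where the knockout disrupts the gene, and whether it is germline or conditional, is not stated in the sources used here (the genotype tag of these libraries reads cre), and counts outside that part check nothing, so the libraries are named by their labels throughout.

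**Figure D2:**
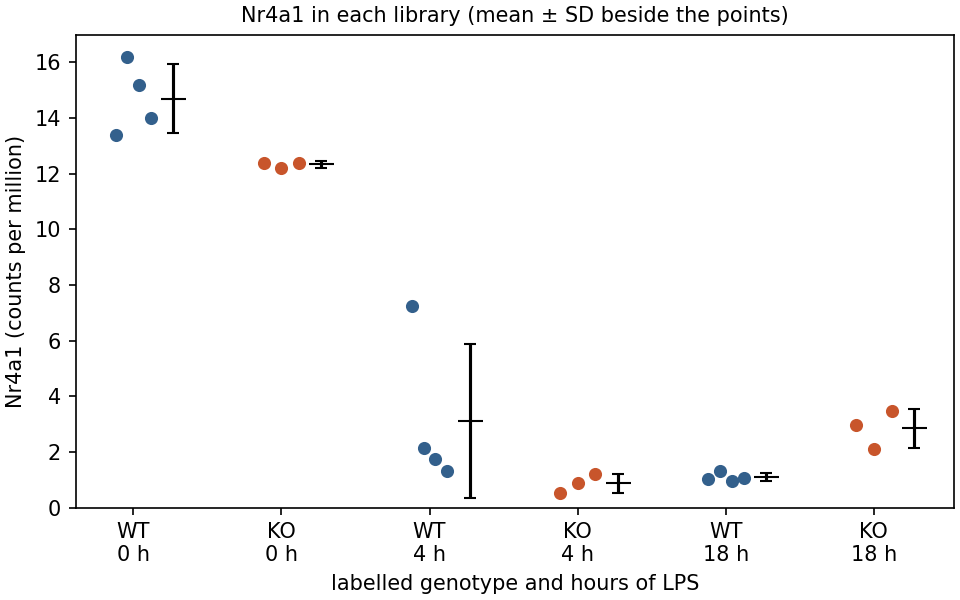
Nr4a1 in CPM (vertical axis) for each library, grouped by labelled genotype and hours of LPS, with the group mean and SD beside the points. Labelled-KO libraries held 12.2 to 12.4 CPM at 0 h, and WT number 1 at 4 h held 7.25 CPM.

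LPS in WT cells raised inflammatory genes within 4 h. Il6, a proinflammatory cytokine, went from 0.281 ± 0.261 to 470 ± 28.4 CPM (SD, n = 4), Nos2, the inducible nitric oxide synthase, from 0.55 ± 0.611 to 781 ± 78.1, and Il12b, a subunit of interleukin 12 and 23, from 0.329 ± 0.332 to 375 ± 125. Acod1, which makes itaconate, rose by 10.01 on the log2 scale, Edn1, the vasoconstrictor endothelin 1, by 9.84, and the adhesion molecule gene Sele by 10.2. Il12a and Steap4 had no count in any WT library at 0 h. With a floor of 3 counts over the group their ratios were 362 and 314, and their 95% counting intervals began at 293 and 254. Gfi1, a transcriptional repressor, rose from 1 count over the group, a ratio of 2810 (95% counting interval 503 to 111000). Cebpa, a myeloid transcription factor, had a log2 fold change of -6.78, Lpin1, a phosphatidate phosphatase, of -6.7, and the cannabinoid receptor gene Cnr2 of -6.77. Plekhg3, Engase, Fam214a, Frat2, Fbxo32 and the receptor gene Cd300lb fell too, with log2 fold changes from -7.35 (Fbxo32) to -6.46 (Cd300lb).

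At 4 h in WT, 9786 of 12529 genes differed from 0 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4403 higher and 5383 lower. Of 43 NF-kB-driven cytokines and mediators 41 rose and 1 fell (41 and 1 adjusted over the list alone), among them Tnfaip3 (6.42), a feedback inhibitor, and Sod2 (5.21), a superoxide dismutase. All 50 interferon-stimulated genes rose (50 adjusted over the list alone), including Irf1 (4.49) and Gbp5 (7.93), and 18 of 22 chemokines rose while 2 fell (18 and 2 adjusted over the list alone), with Ccl3 at 6.62 and Ccl4 at 7.23. These 3 lists stood above the other genes by limma's camera with Benjamini-Hochberg adjustment (adjusted p = 1.8e-17, 1.4e-18 and 7.4e-07). With an estimated correlation the adjusted p were 0.022, 0.35 and 0.26. Actin genes rose in 29 and fell in 9 of 41 (29 and 9 adjusted over the list alone), including Actb (2.46) and Tpm4 (3.19) up and Coro1c (-1.91) down. Integrin and adhesion genes rose in 28 and fell in 10 of 46 (28 and 10 adjusted over the list alone). Both lists were called (camera, Benjamini-Hochberg adjusted p = 0.00095 and 0.0044) and both had an adjusted p = 0.35 with an estimated correlation. The matrix metalloproteinase gene Mmp14 rose by 4.61, the mechanosensitive channel gene Piezo1 by 1.92, and Nr4a3, a relative of Nr4a1, by 4.77, whereas Idh1, a cytosolic isocitrate dehydrogenase, fell (-1.76). The median log2 fold change of all genes was -0.17 with TMM factors, -0.1 with median-of-ratios factors and -0.52 with upper-quartile factors, so changes are read relative to that shift. The share of higher calls went from 45% to 32.6% with upper-quartile factors. Camera called 12 lists here and 49 over the 4 LPS comparisons, and 5 of 60 shuffles of the libraries, the real one included, called as many as 49. Shuffled groups could hold unequal shares of the times and keep part of the LPS effect, so the shuffles cannot decide on chance.

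At 18 h in WT, 8913 genes differed from 0 h by the edgeR test, 4359 higher and 4554 lower. The acute phase gene Saa3 reached 8561 CPM from 11.3 (log2 fold change 9.58), the chemokine gene Ccl5 rose by 8.85, Cxcl11 by 9.84, Slfn4 by 9.37, Tarm1 by 9.5, Upp1 by 8.79 and the lipase gene Lipg by 9.48. Il23r, an interleukin 23 receptor chain, rose from 2 counts over the group, a ratio of 1340 (370 to 11100). Gpr34 (-8.2), Samd4 (-7.8), Rasgrp3 (-7.75), Gprc5c (-7.69), Angptl4 (-7.44) and the prostaglandin-degrading enzyme gene Hpgd (-8.35) fell, and the transporter gene Slco2b1 fell to 1 count over the group, a ratio of 5280 (947 to 209000). Cell cycle genes fell in 35 and rose in 4 of 42 (35 and 4 adjusted over the list alone), with Kif11 at -3.04 and Cenpa at -4.77. Of 43 NF-kB genes 37 were above 0 h and 3 below (37 and 3 adjusted over the list alone). For these lists camera with Benjamini-Hochberg adjustment gave adjusted p = 9.3e-07 and 5.3e-14, or adjusted p = 0.31 and 0.036 with an estimated correlation. LXR target and lipid handling genes fell in 21 and rose in 3 of 27 (21 and 3 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.0012, adjusted p = 0.33 with an estimated correlation), among them Lipa (-2.17), while the nuclear receptor gene Nr1h3 rose by 3.71. The share of higher calls was 48.9%, and 38.6% with upper-quartile factors.

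In labelled-KO cells LPS changed 9394 genes at 4 h (4196 higher, 5198 lower) and 9143 at 18 h (4317 higher, 4826 lower) by the same test. Of the rises at 4 h, 3974 were shared with WT, against 1474.6 for independent lists, and 4815 of the falls, against 2233.3. At 18 h 3748 rises and 3920 falls were shared, against 1501.9 and 1754.1. Calls of opposite direction numbered 10 at 4 h and 78 at 18 h. In labelled KO the log2 fold changes at 4 h were 11.49 for Acod1, 9.38 for Edn1 and -8.38 for Cebpa. Of 43 NF-kB genes 42 rose and 1 fell at 4 h, and 41 rose and 0 fell at 18 h (the same counts adjusted over the list alone). These lists were called by camera with Benjamini-Hochberg adjustment (adjusted p = 8.2e-18 and 9.7e-17) and had an adjusted p = 0.022 at both times with an estimated correlation. The share of higher calls was 44.7% at 4 h and 47.2% at 18 h, and 33.4% and 37.7% with upper-quartile factors.

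Before LPS, labelled-KO cultures held fewer transcripts of the cell cycle and more of neutrophil granules than WT cultures. Which cells in the cultures held these transcripts was not tested. Of 42 cell cycle genes 34 were lower and none higher (40 lower adjusted over the list alone), with a median log2 fold change of -1.07. Kif11, a spindle motor, was at -1.58 and the cyclin gene Ccnd1 at -1.24. Nusap1, a spindle protein gene, was 1.99 ± 0.344 CPM in labelled KO (SD, n = 3) against 8.2 ± 0.679 in WT (n = 4), and the kinetochore gene Cenpf 2.39 ± 0.24 against 9.64 ± 2.03. Of 14 neutrophil and granulocyte precursor markers 9 were higher and none lower (12 higher adjusted over the list alone), with a median of 1.99. S100a9 and S100a8, which form calprotectin, reached 30.8 ± 9.53 and 18.4 ± 4.32 CPM against 7.53 ± 2.05 and 5.38 ± 2.02, and Ltf (lactoferrin) and Lcn2 (lipocalin 2) were higher by 2.02 and 2.2 on the log2 scale. Monocyte markers were higher in 3 and lower in 1 of 12 (4 and 2 adjusted over the list alone), with a median of 0.49, and dendritic cell markers higher in 2 of 12 (3 adjusted over the list alone), with a median of 0.41.

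The edgeR test called 499 genes at 0 h, 139 higher and 360 lower in labelled KO, 225 of them by at least 2-fold. The cell cycle and neutrophil lists were called by camera with Benjamini-Hochberg adjustment (adjusted p = 1.7e-42 and 4.8e-17) and held with an estimated correlation (adjusted p = 0.0015 and 0.018). The monocyte and dendritic cell lists were called higher too (adjusted p = 0.025 and 0.013 by camera with Benjamini-Hochberg adjustment, adjusted p = 0.29 and 0.22 with an estimated correlation). The monocyte call ended without labelled-KO number 4 (adjusted p = 0.072, 1 gene higher) and with the stromal covariate (adjusted p = 0.15) or without the library of highest stromal mean in each group (adjusted p = 0.069), and the dendritic cell call ended without number 2 (adjusted p = 0.061, 0 genes higher). Without labelled-KO number 4 at 0 h 21 cell cycle genes were lower, and 19 without the library of highest stromal mean in each group. The mean log2 CPM of the neutrophil markers was 2.13 to 2.63 in labelled KO and 0.63 to 1.26 in WT. Cd5l, a secreted macrophage survival protein gene (chromosome 3, 87357881 to 87371074), had the largest fall among well expressed genes, from 388 ± 31.3 to 11.7 ± 1.52 CPM (log2 fold change -5.05, SE 0.17, adjusted p = 2.1e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Eya1, a developmental phosphatase gene, was at -4.75, Nxpe4 at -2.73, Cep55, needed for the last step of cell division, at -2.06 and Fcrl1 at -2.04. Ifi202b, an interferon-inducible gene (chromosome 1, 173962569 to 173982844), went from 7 counts over all WT libraries to 148 ± 83.5 CPM, a ratio of 2320 (1130 to 5770). Trim12a (-4.79), Trim30d (-3.14) and Trim5 (-2.7) were lower, and all 4 of these genes have near-identical relatives, so their values are uncertain. Tnfrsf10b, a death receptor gene, was higher by 2.98, Kcnj10, a potassium channel gene, by 2.34, and Adra1a, an adrenergic receptor gene, by 1.84. Chil3, a chitinase-like protein gene, was higher by 1.78, a call that ended without the library of highest stromal mean in each group (1.55). Lox, which crosslinks collagen, was higher by 2.42, but its call ended in 6 of 7 fits that left out a library (2.11 to 2.57), with limma-voom (2.83), the replicate block (2.3) and summed transcripts (2.45), and with the stromal covariate (1.25). Of the fixed genes Tnf was lower (-0.93), a call that ended without labelled-KO number 2 (-0.85) or 4 (-0.78). It also ended with only the 0 h libraries fitted (-0.94), with the stromal covariate (-0.65) and without the library of highest stromal mean in each group (-0.88). Stromal markers had a median of 1.8 (0 passed over all genes, or 7 without WT number 2; 1 higher adjusted over the list alone), and Col1a2, a collagen I chain, stood at 39.5, 53.7 and 72.7 CPM in labelled KO and at 0.656 to 41.5 in WT. The stromal list was called by camera with Benjamini-Hochberg adjustment (adjusted p = 1.3e-05, adjusted p = 0.54 with an estimated correlation). The count of 499 fell to 322, 318 and 317 without labelled-KO number 2, 3 or 4.

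At 4 h of LPS the labelled-KO cells differed from WT in few of the induced inflammatory genes. Tnf (2937 ± 60.1 CPM in labelled KO, n = 3; 2549 ± 367 in WT, n = 4), Il6 (447 ± 102; 470 ± 28.4), Nos2 (867 ± 99.1; 781 ± 78.1) and Il1b (2059 ± 409; 2245 ± 250) did not pass. Higher in labelled KO were Lima1, an actin-bundling protein gene (513 ± 49.7 CPM against 73.6 ± 5.21, log2 fold change 2.8, SE 0.08), Slc16a1, the lactate transporter MCT1 (287 ± 20.7 against 46 ± 11.1), and Tnfrsf10b (17.6 ± 0.846 against 1.08 ± 0.353). Lower were Cd5l (8.4 ± 2.11 against 343 ± 39.1), Ddx58, which encodes the RNA sensor RIG-I (436 ± 16.2 against 1300 ± 187), and the palmitoyltransferase gene Zdhhc2 (5.1 ± 0.984 against 24 ± 4.73).

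In all, 697 genes passed at 4 h, 359 higher and 338 lower, 177 of them by at least 2-fold. Mtus1 (2.25), the vinculin-binding adaptor gene Sorbs3 (2.23), Adra1a (2.44), Pou6f1 (1.75), the immediate early gene Egr3 (2.47) and Depp1 (a ratio of 31.7, interval 20 to 53.3) were also higher, while Adhfe1 (-1.57), Rhobtb2 (-1.55) and the centromere chaperone gene Hjurp (-1.52) were lower. WT number 1 held 2.7 CPM of Egr3, against 0.366 to 0.582 in the other WT libraries. Ifi202b (1741 ± 623 CPM against 1.29 ± 1.19), Trim12a (-4.91), Trim30b (-2.1), Ifi208 (-2.5) and Rps3a1 (-1.5) have near-identical copies and are uncertain, and the call of Ifi208 ended in 6 of 7 fits that left out a library (-2.62 to -2.03). It also ended with median-of-ratios (-2.48) or upper-quartile factors (-2.48), with only the 4 h libraries fitted (-2.48), with summed transcripts (-2.5) and with the stromal covariate (-2.48). Of 42 cell cycle genes 12 were lower and 1 higher (17 and 3 adjusted over the list alone), Mcm2 among them (-1.18), and 7 and 5 were lower without WT number 4 or labelled-KO number 4. Cholesterol synthesis genes were lower in 3 and higher in 0 of 23 (11 lower adjusted over the list alone). Their mean was 4.86 log2 CPM in WT number 1, against 4.03 to 4.16 in the other WT libraries and 3.86 to 3.97 in labelled KO. The count was 0 without WT number 1 or labelled-KO number 2 or 4, 1 without labelled-KO number 3 and 7 without WT number 4. Of 43 NF-kB genes 5 were higher (6 adjusted over the list alone), including the costimulator gene Cd80 (0.58), and 1 to 4 as each 4 h library was left out. Camera with Benjamini-Hochberg adjustment gave adjusted p = 3.9e-06, 0.00021 and 0.046 for these 3 lists, or adjusted p = 0.29, 0.56 and 0.58 with an estimated correlation, and the NF-kB call ended without WT number 1, 2 or 4 or labelled-KO number 3 or 4, with the replicate block (adjusted p = 0.054) and without the library of highest stromal mean in each group (adjusted p = 0.15). Neutrophil and granulocyte precursor markers had a median of 0.75 (1 of 14 higher, 7 higher adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 2.3e-05, adjusted p = 0.29 with an estimated correlation). The number higher was 0 without WT number 1 or 2 or labelled-KO number 2 or 4, 3 without labelled-KO number 3 and 4 without WT number 4. Stromal markers had a median of 2.64 (0 passed over all genes, 10 higher adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.00077, adjusted p = 0.58 with an estimated correlation, and adjusted p = 0.078 without labelled-KO number 4), and Col1a2 stood at 11, 39.2 and 168 CPM in labelled KO and at 1.1 to 23.7 in WT. Mmp14 was lower (661 ± 53.9 against 901 ± 107 CPM, -0.45), a call lost without labelled-KO number 2 (-0.45) or 3 (-0.39). The count of 697 fell to 389 and 278 without labelled-KO number 2 or 4, and to 269 when only the 4 h libraries were fitted, which also ended the call of Mmp14 (-0.44). In fits chosen after seeing the data it was 412 with the stromal list mean as a covariate, 267 without labelled-KO number 4 at every time and 141 without the library of highest stromal mean in each group, where 4 cell cycle genes were lower. Camera called 15 lists at 0 h, 10 at 4 h and 16 at 18 h between the labelled genotypes.

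After 18 h of LPS, inflammatory genes stood higher in labelled KO than in WT. Nos2 was 723 ± 174 CPM (SD, n = 3) against 142 ± 33.7 (n = 4), Il6 80 ± 20.2 against 19.7 ± 3.37, and Il1b 2139 ± 392 against 936 ± 167. Of 43 NF-kB genes 29 were higher and none lower (31 higher adjusted over the list alone), with a median log2 fold change of 0.73 and with the costimulator genes Cd86 (1.27) and Cd80 (1.33) among them. Of 30 immediate early genes, which respond first to a stimulus, 19 were higher (21 higher and 1 lower adjusted over the list alone), such as Dusp5 (1.7), a MAP kinase phosphatase gene, and Zfp36 (0.68), which speeds decay of cytokine mRNA. The relatives of Nr4a1 were higher too, Nr4a2 by 1 and Nr4a3 by 2.87. In WT Nr4a3 stood at 0.322 CPM in number 3 and at 0.0391 to 0.061 in the other libraries, near the floor, so its fold is uncertain.

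Chemokine genes were higher in 10 of 22 (11 adjusted over the list alone), Ccl3 (0.98) and Cxcl2 (0.98) among them, and interferon-stimulated genes in 24 of 50 with 1 lower (27 and 1 adjusted over the list alone), with Gbp5 at 1.27 and Ddx58 at -0.75. The interferon-stimulated count was 15 without labelled-KO number 4 and, in fits chosen after seeing the data, 14 with the stromal covariate and 12 without the library of highest stromal mean in each group, where 5 chemokine genes and 4 neutrophil markers were higher and the call of Ddx58 ended (-0.73). Of 15 genes of antigen presentation by MHC class II 8 were higher (9 adjusted over the list alone). Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.5e-11 for NF-kB, 6.7e-09 for immediate early, 0.0017 for chemokine, 1.6e-06 for interferon-stimulated and 1.6e-05 for MHC class II genes. With an estimated correlation these were adjusted p = 0.06, 0.06, 0.52, 0.58 and 0.35. The neutrophil markers were higher in 9 of 14 (12 adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 0.00012, adjusted p = 0.29 with an estimated correlation). Tnf (218 ± 47.2 against 216 ± 23.3 CPM) and Il12b (25.6 ± 6.25 against 19.2 ± 5.08) did not pass, and Ccl2 (0.62) passed, a call that ended without labelled-KO number 3 (0.56), with the stromal covariate (0.62) and without the library of highest stromal mean in each group (0.65).

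Matrix genes were also higher at 18 h, unevenly among the libraries. Of 50 extracellular matrix genes 30 were higher and 1 lower (33 and 1 adjusted over the list alone), with Vcan at 1.59 and the urokinase receptor gene Plaur at 1.44. Of 15 stromal and fibroblast markers 14 were higher (14 adjusted over the list alone), with a median of 3.61, and of 24 targets of the mechanosensitive MRTF-SRF and YAP regulators 15 (16 adjusted over the list alone), such as the focal adhesion gene Zyx (0.84). Camera with Benjamini-Hochberg adjustment gave adjusted p = 2.1e-06, 0.00089 and 0.00013, or adjusted p = 0.52, 0.58 and 0.52 with an estimated correlation. Col1a2 stood at 14.6, 70.2 and 325 CPM in labelled-KO numbers 2, 3 and 4, and at 3.57 to 21.7 in WT. Timp3 (27.4 ± 34.7 CPM against 1.07 ± 0.549), Postn (4.46), Fbln2 (4.17), Nid1 (4.16), Sparc (3.87), Loxl2 (3.86), Ccn2 (3.73) and Acta2 (3.34), genes of matrix proteins and of contractile cells, each lost its call without the 18 h library of labelled-KO number 4 (2.19 to 3.01), and Tnc (4.07) did not. With the stromal covariate 7 of these calls ended (0.02 to 1.11), while Postn and Tnc passed. Leaving out number 4 at every time ended the calls of Nid1, Sparc, Loxl2, Ccn2 and Acta2, and limma-voom that of Acta2 (2.89). Without the 18 h library of labelled-KO number 4, 13 matrix genes, 2 stromal markers and 5 MRTF-SRF and YAP targets were higher. With the stromal covariate 11 matrix genes were higher and 1 lower, and 5 MRTF-SRF and YAP targets were higher, a list that camera no longer called (Benjamini-Hochberg adjusted p = 0.12). The covariate itself holds 7 genes of the matrix list and 2 of the MRTF-SRF and YAP list, so these were adjusted in part for themselves. In that fit 26 NF-kB, 17 immediate early, 8 chemokine and 8 MHC class II genes were higher.

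**Figure D3:**
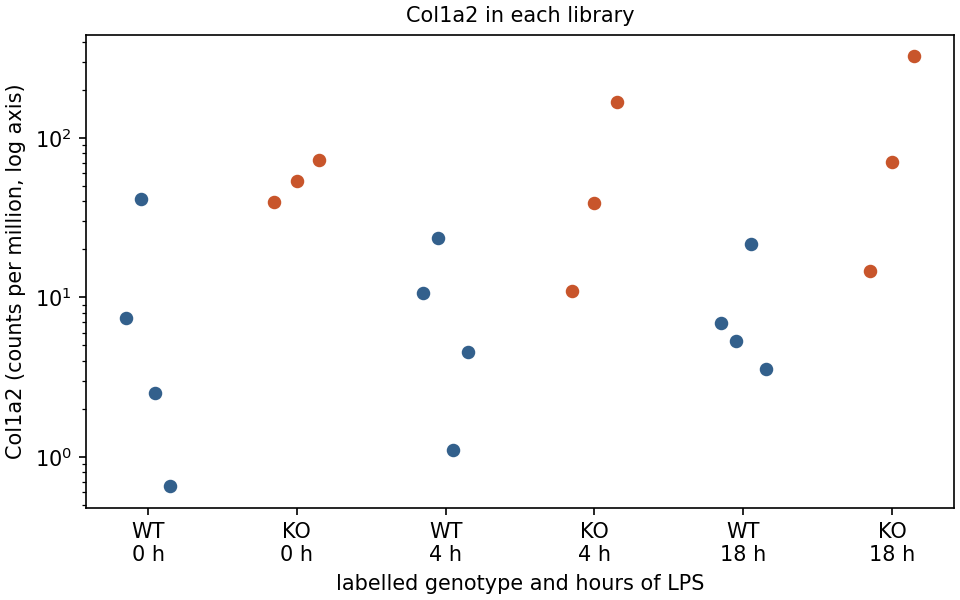
Col1a2 in CPM (vertical log axis) for each library by labelled genotype and hours of LPS. At 18 h labelled-KO libraries held 14.6, 70.2 and 325 CPM, and WT libraries 3.57 to 21.7.

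Genes of the mitochondrial citric acid (TCA) cycle and of ribosomes were lower at 18 h. Of 31 TCA cycle genes 13 were lower and 1 higher (14 and 1 adjusted over the list alone), including Idh2 (-1.11) and Idh3a (-0.97), and the fixed gene Idh1 was lower by a log2 fold change of -0.31. Of 35 ribosomal protein genes 24 were lower and 1 higher (27 and 1 adjusted over the list alone), with Rps18 at -0.54 and Rpl14 at -0.44, all uncertain because such genes have many near-identical copies. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.00086 and 5.1e-07, or adjusted p = 0.29 and 0.52 with an estimated correlation. In fits chosen after seeing the data the lower TCA cycle and ribosomal genes numbered 5 and 14 with the stromal covariate, which also ended the call of Idh1 (-0.28), and 7 and 15 without the library of highest stromal mean in each group, which ended it too (-0.31). Cd5l (1.58 ± 0.437 against 65.5 ± 11 CPM), Mcm2 (-1.71), a DNA replication helicase gene, Spats2 (-2.79), the ceramide synthase gene Cers5 (-1.74), the actin-capping gene Eps8 (-2.72) and Cd244a (-1.75) were lower, as was the leukotriene receptor gene Cysltr2, with 6 counts over the labelled-KO libraries (a ratio of 51.2, interval 23.4 to 140).

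The title of the study concerns the mechanics of macrophages, and its gene groups moved both ways at 18 h. Actin genes were higher in 14 and lower in 4 of 41 (14 and 4 adjusted over the list alone), podosome genes in 9 and 4 of 30 (10 and 4 adjusted over the list alone), and integrin and adhesion genes in 11 and 7 of 46 (11 and 7 adjusted over the list alone). None of the 3 lists was called by camera with Benjamini-Hochberg adjustment (adjusted p = 0.062, 0.059 and 0.19). Without labelled-KO number 4 the higher genes numbered 7, 5 and 7, and with the stromal covariate 7, 5 and 6 (1, 2 and 4 lower). Actin genes were higher in 9 without WT number 2 and lower in 2 without labelled-KO number 2 or 3, and integrin and adhesion genes lower in 4 without WT number 2 or 4 or labelled-KO number 3 and in 2 without labelled-KO number 2. Vcam1 (1.6) and Src (0.68) were higher, and Tagln2 (-0.82), Fgd2 (-0.96) and Itga6 (-0.84) lower. The call of Tagln2 ended without the library of highest stromal mean in each group (-0.78). Spp1 (osteopontin) was higher, 1360 ± 284 against 822 ± 91.8 CPM (0.72), a call that ended with the stromal covariate (0.41). Itgb3 (1.4), Mmp9 (1.14) and Mmp12 (0.84) were higher with calls that ended without labelled-KO number 4 (0.8 for Itgb3, 0.82 for Mmp9), WT number 4 (1.23 for Itgb3), or WT number 1 or labelled-KO number 3 (0.61 to 0.73 for Mmp12). All 3 calls also ended with the stromal covariate (0.83, 0.53 and 0.9). Those of Itgb3 and Mmp9 ended without the library of highest stromal mean in each group (1.08 and 0.76), and that of Itgb3 with limma-voom (1.25) and with only the 18 h libraries fitted (1.37). Actb (14260 ± 681 against 15260 ± 449 CPM), Myh9 (953 ± 116 against 832 ± 71.7), Piezo1 (197 ± 6.42 against 183 ± 9.28) and Itga9 (88.3 ± 3.47 against 82.9 ± 5.73) did not pass.

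At 18 h the edgeR test called 4034 genes, 2074 higher and 1960 lower, 971 of them by at least 2-fold. Higher calls made up 51.4% of these with TMM factors, 59.5% with median-of-ratios factors and 44.6% with upper-quartile factors, so the direction with more calls depended on the scaling. The count was 2673 without labelled-KO number 4 at 18 h. In fits chosen after seeing the data it was 2333 with the stromal covariate, 2527 without labelled-KO number 4 at every time and 2238 without the library of highest stromal mean in each group.

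**Figure D4:**
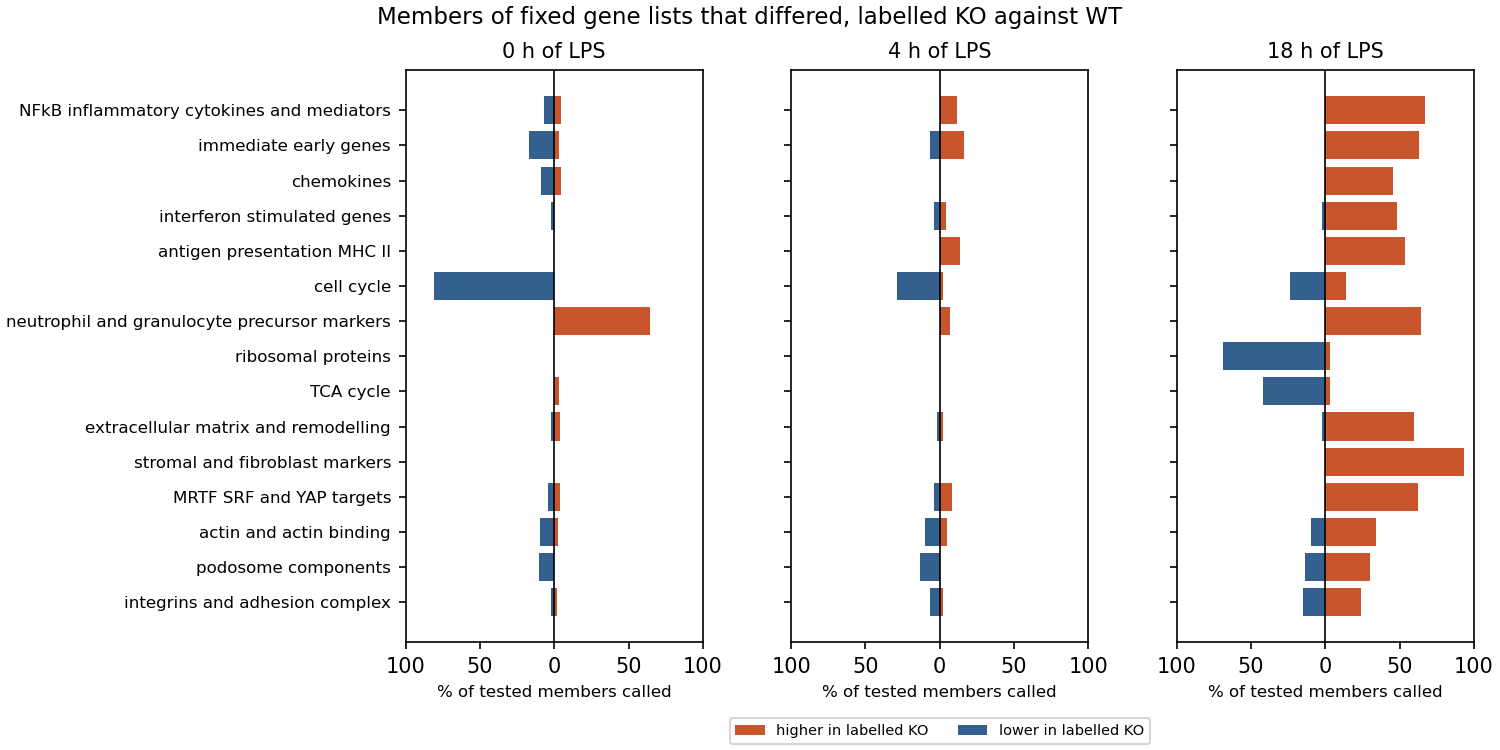
Percent of tested members (horizontal axis) of 15 fixed gene lists called higher (right) or lower (left) in labelled KO than in WT, at 0, 4 and 18 h of LPS. Cell cycle genes were lower in 34 of 42 at 0 h, and NF-kB genes higher in 29 of 43 at 18 h.

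The test of whether LPS acted differently in the labelled genotypes called 100 genes at 4 h, 75 more positive in labelled KO and 25 more negative. Slc16a1 had an interaction of 2.89 on the log2 scale (SE 0.24), Mtus1 of 1.99, Rhobtb2 of -2.02, Ppfibp2 of -1.38 and the inhibitory Fc receptor gene Fcgr2b of -1.32. Cell cycle genes were positive in 9 of 42 (17 positive and 1 negative adjusted over the list alone; camera with Benjamini-Hochberg adjusted p = 9.5e-13, adjusted p = 0.078 with an estimated correlation), and in 5 and 4 without labelled-KO number 2 or 4 at 0 h and 3 without number 4 at 4 h. Between the labelled genotypes cell cycle genes had a median of -1.07 at 0 h and -0.45 at 4 h. Their interaction thus carries a difference present before LPS. The count of all genes was 63 without labelled-KO number 2 at 0 h, 65 without number 4 at 4 h and 204 with DESeq2. In fits chosen after seeing the data it was 45 without labelled-KO number 4 at every time, where Fcgr2b (-1.25) did not pass, and 26 without the library of highest stromal mean in each group.

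By 18 h the LPS response differed for 2202 genes, 1074 positive and 1128 negative. Positive calls made up 48.8% with TMM factors, 58.6% with median-of-ratios factors and 41.8% with upper-quartile factors, so here too the direction with more calls depended on the scaling. Nos2 had an interaction of 3.79 (SE 0.95) whose call ended with limma-voom (2.49), Il1b of 1.7 (SE 0.3), Nr4a2 of 1.37, Nr4a3 of 2.48, Prag1 of 3.63 and Spp1 of 1.19, while Bmp1 (-2.53), Fscn1 (-1.99), an actin-bundling protein gene, and Idh1 (-0.53) were negative. The value of Nr4a3 rests on WT libraries near the floor at 18 h. Il6 (3.02), Tnf (0.95) and Nr4a1 (1.6) passed, with calls that ended in 4, 3 and 12 of the 14 fits that left out a library (2.43 to 2.75, 0.78 to 0.87 and 1.42 to 1.72). Immediate early genes were positive in 17 of 30 (18 adjusted over the list alone), with Dusp1 at 1.54, and NF-kB genes positive in 23 and negative in 1 of 43 (26 and 1 adjusted over the list alone). Both lists were called by camera with Benjamini-Hochberg adjustment (adjusted p = 2.5e-11 and 9.5e-13), and both held with an estimated correlation (adjusted p = 0.049). Cell cycle genes were positive in 22 and negative in 2 of 42 (26 and 3 adjusted over the list alone), with Ccnd1 at 1.35, and podosome genes positive in 9 and negative in 1 of 30 (11 and 4 adjusted over the list alone), with Myo1e at 0.7. The last 2 lists had, by camera with Benjamini-Hochberg adjustment, adjusted p = 1.8e-10 and 0.0042, or adjusted p = 0.12 and 0.078 with an estimated correlation. Between the labelled genotypes cell cycle genes had a median of -1.07 at 0 h and 0.04 at 18 h (6 higher, 10 lower). Their interaction thus carries a difference present before LPS. Tnf too was lower in labelled KO at 0 h and did not pass at 18 h. Podosome and immediate early genes were called lower at 0 h by camera with Benjamini-Hochberg adjustment (adjusted p = 0.015 and 0.041). With an estimated correlation these were adjusted p = 0.22 and 0.56. Their medians were -0.09 and -0.05 at 0 h, and 0.19 and 0.68 at 18 h. Part of these 2 interactions may thus also be a difference present before LPS. The count was 1275 without labelled-KO number 4 at every time, with 5 podosome genes positive, and 899 without the library of highest stromal mean in each group, with 10 immediate early, 13 cell cycle and 4 podosome genes positive. Both fits were chosen after seeing the data, and 2 of 35 splits of the libraries called as many lists.

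Across the 3 times, 98 genes differed in a single direction, 37 higher and 61 lower in labelled KO, against 2.18 for independent lists. Cd5l, Trim12a and Ifi202b were among them. Of the 98, 25 lay on chromosome 3, 14 on chromosome 6, 10 on chromosome 1, 8 on chromosome 14, 7 on chromosome 7 and 6 on chromosome 15, which holds Nr4a1. Among 56 tested neighbours of Nr4a1 on distal chromosome 15, 2 were higher and 6 lower at 0 h (3 and 9 adjusted over the list alone). At 4 h 4 were higher and 3 lower (4 and 6 adjusted over the list alone). At 18 h 9 were higher and 13 lower (10 and 13 adjusted over the list alone), Lima1 (0.54) and Cers5 (-1.74) among them. There 4 were higher without labelled-KO number 4 and 8 lower without number 3. Of all tested genes 4% were called at 0 h, 5.6% at 4 h and 32.2% at 18 h. Camera with Benjamini-Hochberg adjustment did not call the list at 18 h (adjusted p = 0.64). It looks for a shift in a single direction, so it cannot decide for neighbours that move both ways.

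**Figure D5:**
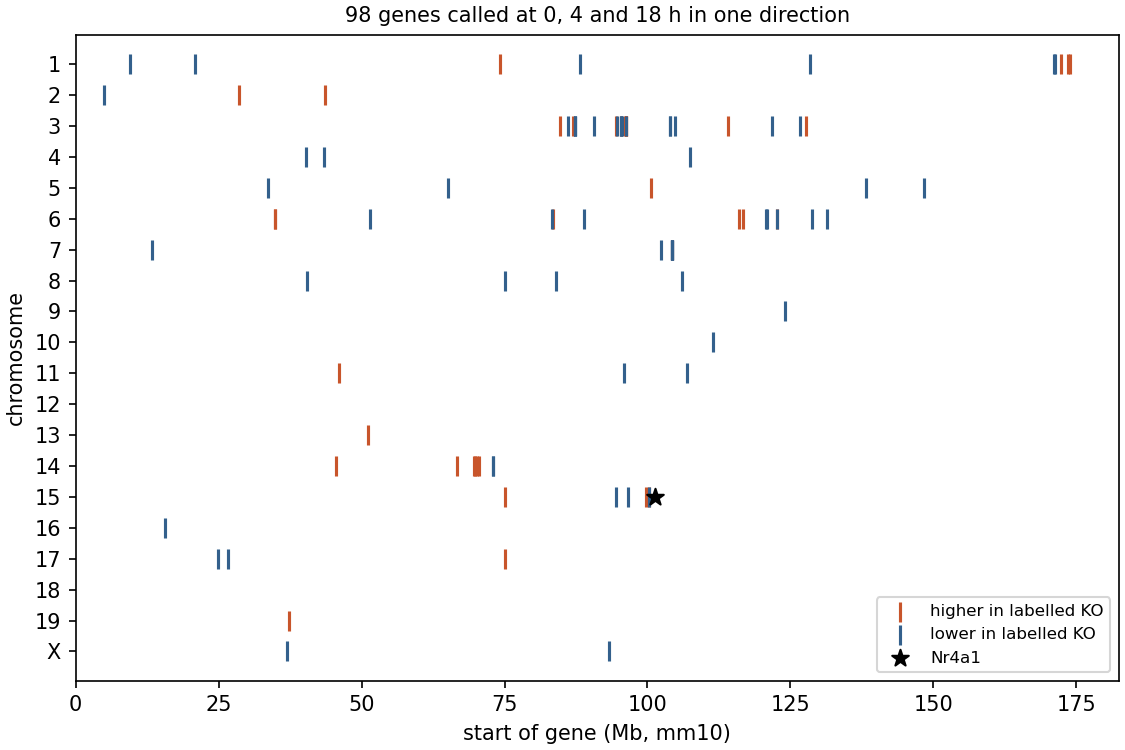
Start position in megabases on mm10 (horizontal axis) and chromosome (vertical axis) of the 98 genes called in a single direction at 0, 4 and 18 h, coloured by direction, with a star for Nr4a1. Chromosome 3 holds 25 of them and chromosome 15 holds 6.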

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

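The tests of linked segments, of the stromal covariate and of the early LPS response were chosen after the results were seen, as were summed transcripts and the fits without labelled-KO number 4 or the highest-stromal libraries.

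In 13 of 126 groups examined 1 library stood far from the others, and chance flags about 1 group in 20. WT number 1 at 4 h held 7.25 CPM of Nr4a1 (others 1.3 to 2.16), 2.7 of Egr3 (0.366 to 0.582), 17.3 of Pou6f1 (11.2 to 11.9), 757 of Ifi208 (337 to 360) and 1580 of Ddx58 (1200 to 1220). WT number 1 at 18 h held 726 CPM of Myh9 (others 859 to 884) and 24.7 of Il6 (17.5 to 18.6). WT number 3 at 18 h held 0.322 CPM of Nr4a3 (0.0391 to 0.061), 1.45 of Nid1 (0.17 to 0.366) and 4.1 of Tnc (1.87 to 2.11). WT number 2 held 2160 CPM of Spp1 at 0 h (1360 to 1420) and 664 of Nos2 at 4 h (814 to 828), and WT number 4 held 1.76 of Ifi202b at 18 h (0.244 to 0.391).

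The response to LPS differed between the labelled genotypes for 100 genes at 4 h and 2202 at 18 h by edgeR's interaction test. At 4 h the log2 interaction was 4.55 for Slamf1 (2 counts in labelled KO at 0 h), 2.89 for Slc16a1, 2.68 for Trim30d, 2.67 for Zdhhc2, 2.45 for Sgo2a, 1.99 for Mtus1, -2.02 for Rhobtb2, -1.95 for Rnd1, -1.82 for Lcn2, -1.46 for Ccl8, -1.38 for Ppfibp2 and -1.32 for Fcgr2b. At 18 h it was 5.29 for Slamf1, 4.32 for Lipg (1 count in labelled KO at 0 h), 3.98 for Car2, 3.79 for Nos2, 3.78 for Trim30d, 3.63 for Prag1, -2.75 for Coro2b (3 counts in labelled KO at 18 h), -2.53 for Bmp1, -2.03 for Sumo2, -1.99 for Fscn1, -1.97 for Ebpl and -1.94 for Rsad1. Among the fixed genes at 18 h it was 3.02 for Il6, 2.48 for Nr4a3, 1.79 for Itgb3, 1.7 for Il1b, 1.6 for Nr4a1, 1.37 for Nr4a2, 1.19 for Spp1, 1.11 for Ccl2, 0.95 for Tnf and -0.53 for Idh1. Of the 14 fits that each left out a library, the call ended for Slamf1 at 4 h in 3 (3.90 to 4.25), Sgo2a at 4 h in 1 (1.47, without labelled-KO number 4 at 4 h), Lcn2 at 4 h in 1 (-1.63, without labelled-KO number 3 at 0 h), Ccl8 at 4 h in 2 (-1.32 to -1.13, without WT number 2 at 0 h, labelled-KO number 2 at 0 h), Lipg at 18 h in 9 (3.93 to 5.94), Car2 at 18 h in 1 (2.06, without WT number 3 at 0 h), Itgb3 at 18 h in 1 (1.19, without labelled-KO number 4 at 18 h), Nr4a1 at 18 h in 12 (1.42 to 1.72), Tnf at 18 h in 3 (0.78 to 0.87) and Il6 at 18 h in 4 (2.42 to 2.75). Other settings ended calls too. With limma-voom these were Slamf1 (4.44), Zdhhc2 (2.54), Sgo2a (2.13), Rnd1 (-2.03) and Ccl8 (-1.40) at 4 h, and Lipg (3.61), Il6 (2.50), Nos2 (2.49) and Itgb3 (1.61) at 18 h, where that of Nr4a1 (1.60) ended with transcripts summed. In fits chosen after seeing the data, leaving out labelled-KO number 4 at every time ended the calls of Slamf1 (3.73), Zdhhc2 (2.87), Sgo2a (1.5), Fcgr2b (-1.25) and Lcn2 (-1.89) at 4 h and of Lipg (5.90), Car2 (3.83), Il6 (2.66), Nr4a1 (1.42), Itgb3 (1.33) and Tnf (0.94) at 18 h. Leaving out the library of highest stromal mean in each group ended those of Slamf1 (3.81), Zdhhc2 (2.77), Sgo2a (1.39), Fcgr2b (-1.28), Ccl8 (-1.64) and Lcn2 (-1.79) at 4 h and of Lipg (6.30), Car2 (4.24), Itgb3 (1.44), Nr4a1 (1.32), Ccl2 (1.01), Tnf (0.98), Idh1 (-0.48) and Coro2b (-2.67) at 18 h. Camera called 28 lists in the 2 interactions.

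No other of the 35 splits of the numbered sets reached the counts of genes between genotypes, which argues against chance for them. A share of 1 of 35 is the smallest these splits can give. The real value and the highest other were 499 and 5 at 0 h, 697 and 31 at 4 h, and 4034 and 1668 at 18 h. For the interactions they were 100 and 1 at 4 h and 2202 and 6 at 18 h. For lists between genotypes they were 41 and 38. A split that called no gene still called 34 lists, so chance is not excluded for that number of lists. The split with 1668 genes at 18 h set WT numbers 1, 2 and 4 against WT number 3 and labelled KO, a structure of the samples that goes partly with genotype. In deviations from group means, WT number 3 at 18 h correlated at 0.34 with WT number 2 at 0 h and at 0.32 with labelled-KO number 4 at 18 h. It correlated at -0.12 with WT number 3 at 0 h, so splits that follow a number across times rest on the labels alone at 18 h. For LPS in WT the real split also called the most genes (9786 and 4 at 4 h, 8913 and 0 at 18 h, 1 of 35 splits each). Every other split mixed 0 h with LPS libraries, so the low counts there add little. In labelled KO the 10 splits are too few for a share under 0.05 (9394 and 0, 9143 and 0). Chance cannot be excluded for the number of lists in the interactions (28 and 28, 2 of 35 splits). For lists changed by LPS (49 and 51, 5 of 60 shuffles) the shuffled groups could hold unequal shares of the times. They could thus keep part of the LPS effect, so these shuffles cannot decide on chance for that number of lists.

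More genes differed between the labelled genotypes at 18 h (4034) than at 0 h (499) or 4 h (697). With every library thinned to the lowest library total the numbers were 421, 547 and 3635, which argues against depth as the cause. With the stromal mean as a covariate they were 408, 412 and 2333. At 18 h that mean was 1.29 to 4.89 log2 CPM in labelled KO and -0.21 to 1.73 in WT, so the fall may reflect lost power. A single mean also need not remove all stromal transcripts. This fit therefore does not settle what part of the count at 18 h, or of its excess, they make up. A slower loss of the early LPS response in labelled KO stays open, since its mean correlation across genes was 0.19 (0.16 to 0.22 over 6 ways of dividing the WT 18 h libraries into equal parts, covariance 0.156), between the bounds set for and against it. An effect of the labelled genotype also stays open.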

How the results depend on the processing

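Alternatives chosen after seeing the data were upper-quartile factors, summed transcripts, the stromal covariate and the fits without labelled-KO number 4 or the highest-stromal libraries. Of 344 values of the counts and lists under alternatives, 303 stayed within 1.5 times or kept their call, and of 17866 values of named genes 16782 did, 939 lost and 27 gained their call and 118 turned. Depth limits what is called, as thinning every library to the lowest total left 421, 547 and 3635 genes between genotypes at 0, 4 and 18 h. Where no cause is named, the cause was not tested.

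Leaving out each library in turn gave 317 to 501 genes at 0 h, 278 to 682 at 4 h and 2673 to 3838 at 18 h between the labelled genotypes, 63 to 128 and 1531 to 2199 in the interactions at 4 h and 18 h, 9574 to 9677 and 8539 to 8732 for LPS in WT, and 9000 to 9097 and 8673 to 8902 in labelled KO. Called lists ran from 36 to 43 between genotypes, 47 to 52 for LPS and 22 to 29 in the interactions. The 4 h count between genotypes was 269 with only the groups compared (fewer libraries), 412 with the stromal covariate, 267 without labelled-KO number 4 and 141 without the highest-stromal libraries, and the 18 h count was 2333, 2527 and 2238 in the last 3. The interaction count at 4 h was 204 with DESeq2, 45 without labelled-KO number 4 and 26 without the highest-stromal libraries, and that at 18 h 1275 and 899. With an estimated correlation camera called 2 lists between genotypes, 4 for LPS and 2 in the interactions, and fry called 128 for LPS and 17 in the interactions.

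Nr4a1 between genotypes ran from -0.295 to -0.207 at 0 h, -2.166 to -0.848 at 4 h and 1.164 to 1.518 at 18 h as each library was left out. At 4 h its call was lost with limma-voom (-1.408), duplicateCorrelation (-1.412), only the groups compared (-1.78), without labelled-KO number 4 (-2.166) and without the highest-stromal libraries (-2.285). At 18 h it was lost with the stromal covariate (0.992), without labelled-KO number 4 (1.163) and without the highest-stromal libraries (1.115). With the replicate number as a block Nr4a1 at 4 h was -1.471 and lost its call, and the counts were 498, 609 and 4074 between genotypes and 121 and 2414 in the interactions, none moved by over 1.5 times. The block changed the call of no other count or Nr4a1 value.

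Pdk4, called at 18 h (2.863), was -0.075 with the stromal covariate. Its call also ended in 5 of 7 fits that left out a library (2.434 to 2.944). DESeq2 (2.897), limma-voom (2.71), the replicate block (2.714) and summed transcripts (2.848) ended it too. The other values that turned were not called, with log2 values between -0.125 and 0.274. Mmp12 at 0 h was -0.012 and turned to 0.011 with limma-voom, 0.011 with duplicateCorrelation, 0.037 with the stromal covariate, 0.042 with no highest-stromal libraries, and ran from -0.117 to 0.081 as each library was left out. Cxcl1 at 0 h was 0.133 and turned to -0.282 with the replicate block, and ran from -0.206 to 0.54 as each library was left out. Itga9 at 4 h was -0.045 and ran from -0.106 to 0.023 as each library was left out. Itgb3 at 4 h was 0.038 and turned to -0.035 with the replicate block, -0.005 with transcripts summed, -0.397 with the stromal covariate, -0.221 with no labelled-KO number 4, -0.055 with no highest-stromal libraries, and ran from -0.223 to 0.202 as each library was left out. Mmp9 at 4 h was -0.05 and turned to 0.19 with no labelled-KO number 4, 0.496 with no highest-stromal libraries, and ran from -0.27 to 0.26 as each library was left out. Spp1 at 4 h was 0.004 and turned to -0.018 with no filter, -0.055 with the replicate block, -0.008 with transcripts summed, -0.194 with the stromal covariate, and ran from -0.097 to 0.146 as each library was left out. Il6 at 4 h was -0.072 and turned to 0.045 with the stromal covariate, and ran from -0.27 to 0.05 as each library was left out. Il1b at 4 h was -0.125 and turned to 0.076 with the stromal covariate. Il12b at 4 h was 0.061 and turned to -0.017 with the replicate block, and ran from -0.125 to 0.268 as each library was left out. Nos2 at 4 h was 0.15 and turned to -0.01 with no highest-stromal libraries. Ccl2 at 4 h was -0.079 and turned to 0.045 with no labelled-KO number 4, 0.168 with no highest-stromal libraries, and ran from -0.281 to 0.045 as each library was left out. Cxcl1 at 4 h was 0.135 and turned to -0.049 with the replicate block, and ran from -0.183 to 0.462 as each library was left out. Nr4a2 at 4 h was -0.058 and turned to 0.111 with no labelled-KO number 4, 0.076 with no highest-stromal libraries, and ran from -0.33 to 0.112 as each library was left out. Tnf at 18 h was 0.018 and turned to -0.039 with the replicate block, -0.024 with upper-quartile factors, and ran from -0.157 to 0.157 as each library was left out. Cxcl1 at 18 h was 0.136 and turned to -0.156 with the replicate block, -0.066 with no highest-stromal libraries, and ran from -0.098 to 0.524 as each library was left out. Myh9 in the interaction at 4 h was -0.002 and turned to 0.015 with median-of-ratios factors, 0.015 with DESeq2, 0.011 with only the groups compared, 0.003 with the replicate block, 0.009 with upper-quartile factors, 0.009 with the stromal covariate, 0.062 with no labelled-KO number 4, 0.007 with no highest-stromal libraries, and ran from -0.062 to 0.044 as each library was left out. Cxcl1 in the interaction at 4 h was 0.002 and turned to -0.016 with no filter, -0.208 with limma-voom, -0.004 with transcripts summed, -0.008 with the stromal covariate, -0.222 with no labelled-KO number 4, -0.324 with no highest-stromal libraries, and ran from -0.416 to 0.33 as each library was left out. Nr4a3 in the interaction at 4 h was -0.005 and turned to 0.017 with median-of-ratios factors, 0.01 with DESeq2, 0.086 with limma-voom, 0.008 with only the groups compared, 0.017 with the replicate block, 0.105 with transcripts summed, 0.008 with upper-quartile factors, 0.331 with no labelled-KO number 4, 0.255 with no highest-stromal libraries, and ran from -0.327 to 0.247 as each library was left out. Itga9 in the interaction at 18 h was -0.066 and ran from -0.125 to 0.003 as each library was left out. Mmp9 in the interaction at 18 h was 0.274 and turned to -0.274 with no highest-stromal libraries, and ran from -0.121 to 0.504 as each library was left out. Cxcl1 in the interaction at 18 h was 0.003 and turned to -0.006 with no filter, -0.404 with limma-voom, -0.037 with upper-quartile factors, -0.294 with no labelled-KO number 4, -0.584 with no highest-stromal libraries, and ran from -0.411 to 0.391 as each library was left out.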

Other observations

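The tests of linked segments, of the segment around Nr4a1 and of stromal cells were chosen after the results were seen, as were upper-quartile factors and the fits without labelled-KO number 4 at every time or the highest-stromal libraries.

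At 18 h of LPS, further groups differed between labelled KO and WT. Apoptosis regulators were higher in 15 and lower in 2 of 31 (15 and 3 adjusted over the list alone), with the protease gene Casp1 (0.77) higher and Bid (-0.97) lower. Glycolysis and hypoxia genes were higher in 11 and lower in 3 of 33 (12 and 3 adjusted over the list alone), among them the hexokinase gene Hk1 (0.78) and Pfkfb3 (1.11). Cholesterol synthesis genes were lower in 7 of 23 (7 adjusted over the list alone), such as Dhcr7 (-1.35). Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.0012, 0.021 and 0.041, or adjusted p = 0.22, 0.58 and 0.72 with an estimated correlation. Without labelled-KO number 4 at 18 h 7 glycolysis genes were higher and the call ended (adjusted p = 0.12), and with the stromal covariate 7 (adjusted p = 0.051). That call also ended without the library of highest stromal mean in each group (adjusted p = 0.18). Cholesterol synthesis genes were lower in 4 without WT number 4 or labelled-KO number 2, and in 2 without labelled-KO number 4 or with the stromal covariate, and the cholesterol call ended without any of these 3 libraries or WT number 1 (adjusted p up to 0.095) and with the replicate block (adjusted p = 0.11). Alternative activation and anti-inflammatory genes were higher in 12 and lower in 1 of 28 (13 and 1 adjusted over the list alone), with Vegfa (1.52) higher and Pparg (-0.59) lower, and osteoclast markers were higher in 6 and lower in 1 of 10 (6 and 1 adjusted over the list alone), with Car2 (2.85) higher and Tnfrsf11a (-0.31) lower. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.013 and 0.046, or adjusted p = 0.29 and 0.41 with an estimated correlation. The first call ended without the library of highest stromal mean in each group, a fit chosen after seeing the data (adjusted p = 0.057, 8 genes higher), and 2 of its genes were lower without labelled-KO number 3. The osteoclast call ended without WT number 1 (adjusted p = 0.055) or labelled-KO number 2 (adjusted p = 0.052) or 4 (adjusted p = 0.091, 3 genes higher), with the replicate block (adjusted p = 0.068), and in fits chosen after seeing the data with 3 genes higher each, those with the stromal covariate (adjusted p = 0.11), without labelled-KO number 4 at every time (adjusted p = 0.093) and without the library of highest stromal mean in each group (adjusted p = 0.069), where Tnfrsf11a (-0.24) did not pass.

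The 98 genes called in a single direction at all 3 times lay in clusters. Another of them stood within 2 Mb of 55.1%, against a median of 24.5% (14.3 to 35.7) and a highest of 45.9% over 10000 random sets of tested genes, and no split of the libraries gave any such gene (98 and 0, 1 of 35). Some close neighbours overlap or are related, such as Gm9199 and Cysltr2, Mettl7a1 and Mettl7a3, and Trim genes on chromosome 7. Such genes may share reads, and the random sets do not allow for that. Scaling is argued against by 90 and 95 of the 98 that stayed called under the other 2 scalings, and the segment around Nr4a1 alone is argued against by 6 genes on its chromosome. With the stromal covariate 66 of the 98 stayed called at all 3 times. Strain segments that differ between the WT and labelled-KO animals may account for part of these genes, a hypothesis found on these data and not tested with sequence. An effect of the labelled genotype on the same genes stays open.

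Extracellular matrix genes were higher in 30 of 50 at 18 h, and all 30 stayed called under both other scalings, which argues against scaling. Within groups, the deviations of the 24 not shared with the stromal list had a median correlation of 0.66 with those of the mean of 9 stromal genes across the 21 libraries (-0.07 to 0.94, 17 of them above 0.5, 0.64 in WT alone, 0 over all tested genes). With the stromal covariate 11 of the 30 stayed called, and 13 matrix genes were higher without labelled-KO number 4 at 18 h. The covariate itself holds 6 of the 30, so these were adjusted in part for themselves. Stromal cells in the cultures may therefore be a source of these transcripts, with Col1a2 at 325 CPM in labelled-KO number 4. Matrix expression by the macrophages themselves was not tested.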
